A study of Drosophila melanogaster with 2 samples.

How the data were processed

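Whole embryos of both sexes, 10 to 24 h old, from a Drosophila melanogaster line carrying CG12769 with a C-terminal GFP tag were studied by ChIP-seq with an antibody against GFP. Per the labels, chromatin was sonicated and the fragments ranged from 200 to 800 bp. The labels give 1 group and 2 biological replicates, numbered 5 and 7, each with 1 library, from separate samples of embryos. There was no treated or untreated contrast, and a control library was not analysed here. Age was taken as 10 to 24 h from the sample source; a separate age field holds a value that cannot be an embryo's age and was not used.

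The authors deposited 4 peak lists in narrowPeak format on the dm6 assembly: 1 for each replicate, 1 for the pooled replicates, and the IDR-thresholded set. Per the labels and the notes deposited with them, each list was made from the alignments of the replicate or replicates and 1 further file that these notes do not describe. The IDR set was derived from the other 3 lists. The aligner, the peak caller, their versions, the filters, the treatment of repeated sequence and the IDR threshold are not given in the sources used here. The deposited signal value of each peak is the peak caller's own, on a scale that is not stated and can differ between lists. It was used only to describe, rank and filter peaks within a list. The deposited −log10 q-value of each peak is the caller's own as well. Its highest value in the IDR set, 4.04, was shared by 5466 peaks, so it was not used for ranking, and the lowest was 2.25. Each replicate list and the pooled list held exactly 30000 peaks, a shared number, so their lower ends do not show where binding ends. No counts of reads were in these lists, so the depth of each library is unknown and no value here carries a depth-based error. Shares of peaks, genes and windows have exact (Clopper-Pearson) 95% intervals, which cover counting error only.

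Coordinates were taken as deposited and are given 1-based. Gene positions came from the Ensembl release 115 annotation of the BDGP6.54 assembly, which has the sequence of dm6; the ends of all peaks lay within its chromosomes. Arms 2L, 2R, 3L, 3R, 4 and X were used, with 18164 genes once transposable elements were left out, of which 13945 were protein-coding, and 23581 distinct TSS positions. The summit of a peak is the position its list gives. Where a peak interval held several summits, each was listed by the authors as a peak of its own and counted as such.

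Replicates were compared by the share of peaks overlapping by at least 1 bp, against 100 random circular shifts along the chromosome, with an exact two-sided binomial test. Each IDR summit was assigned to the first of 7 categories that applied (TSS within 500 bp, 5' UTR, CDS, 3' UTR, noncoding exon, intron, intergenic), and counts were tested against the share of non-N bases by exact binomial tests. Peak strength was tested with Fisher's exact test between the 2143 strongest and the 2143 weakest IDR peaks. Peaks per chromosome arm were tested against non-N bases. For 26 gene lists, the number of genes with an IDR summit within 500 bp of any of their TSSs was tested against all other protein-coding genes (all genes for the lists of RNA genes) with Fisher's exact test. For 25 consensus sequences, read on both strands, windows of 201 bp around summits were tested against windows centred 600 bp to each side that no other IDR peak overlapped. Words of 8 bases present in at least 10 windows were ranked on peaks of odd rank, and the first 10 were tested on peaks of even rank. Multiple tests were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05, and all tests were two-sided unless said otherwise. A p too small for the computer's number range is printed as below 1e-300.

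The tests, the gene lists, the consensus sequences, the rule for named genes and most of the alternative settings below were fixed before the data were examined. Named genes are those nearest to the 25 IDR peaks with the highest value among those within 500 bp of a TSS (ties to the name that sorts first; other genes in reach are given beside them), up to 4 members of each list with the highest value, and CG12769. Peaks among the 10 strongest that lay farther from a TSS are given by position. List names were matched to gene symbols, then to synonyms that name a single gene. For 8 names that this left unmatched or matched wrongly, the gene was then set by hand (for example Delta for Dl and dpy for dp), after a first table of list results had been seen. One listed name, Ugt, stands for a gene family and was left out.

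Alternatives planned in advance were the 2143 strongest IDR peaks, the whole pooled list, and the 8574 strongest peaks of a single replicate (without replicate 5, and without replicate 7); TSS distances of 200 and 1000 bp; protein-coding TSSs only; overlap of the whole peak instead of the summit; 1 gene per peak; TSS positions instead of bases for the chromosome arms; windows of 50 bp to each side; promoters without an IDR peak as background; words of 6 and 7 bases; and a 50% reciprocal overlap, summits within 100 bp or top peaks only for the replicates. Added after seeing the data were a single summit per 1000 bp, gene lists matched on the number of TSSs with 100000 permutations, list names without the matching by hand, and other peak sets for the CG12769 gene.

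The procedures were tested on simulated data. With a made promoter share of 39.5% among 8574 random summits, 39.8% was found, and none of the 7 categories and none of the 6 arms passed with random positions. A made difference of 20 points between strong and weak peaks came back as 18.65 points on average. Gene lists made with 55% of genes bound, against 21% of others, passed in 96% of cases, and 1.67% of the other lists did. A planted 8-base word present in 5% of windows was found first, in 5.5% of test windows, and a planted motif had the lowest p of the 25. A made overlap of 72.1% was found as 72.1%. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.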

Results

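The series measured where in the genome a tagged CG12769 protein was found in whole fruit fly (Drosophila melanogaster) embryos. Flies carried a transgene that expresses CG12769 joined at its C-terminus to green fluorescent protein (GFP), and an antibody against GFP pulled down the protein with the DNA bound to it, which was then sequenced (ChIP-seq). The labels do not say what CG12769 does. Embryos of both sexes were taken 10 to 24 h after laying. There was 1 group with 2 biological replicates, numbered 5 and 7 in the labels, so the comparisons are those between the replicates, between peaks and the rest of the genome, and between strong and weak peaks. Peaks, genes or sequence windows, not animals, were the units of every test, the replicate comparison included, so the p-values describe this peak set and not the spread between animals.

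Each replicate's list held 30000 peaks, as did the list called on the pooled replicates. A further list of 8574 peaks had passed the authors' threshold on the irreproducible discovery rate (IDR), a measure of how well peak ranks match between replicates. These 8574 IDR peaks were the 8574 pooled peaks with the highest value, 28.6% of the pooled list. They covered 2.65 Mb on 6 chromosome arms, against 10.3 Mb for the pooled list, 9.86 Mb for replicate 5 and 10.5 Mb for replicate 7. The value attached to each peak is the authors' own signal. In the IDR set it ran from 169.7 to 16058.3 with a median of 288.9. Read counts were not in the lists analysed here, so the sequencing depth behind each peak is unknown.

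The replicates marked largely the same places in the embryo genome, and strong peaks of one were most often in the other's full list. The promoter shared by CG33111 and eIF4G2, a translation initiation factor gene, held the first-ranked peak in both replicates, and an intron of CG11050 held the second in both. Of the 30000 peaks of replicate 5, 77.3% overlapped a peak of replicate 7 (95% exact interval 76.9 to 77.8). In the other direction the share was 80.7% (80.2 to 81.1). When the peaks were moved to random positions along their chromosomes, 13.9% and 14.2% overlapped on average over 100 moves (exact binomial test, two-sided, p below 1e-300 in both directions). The share found in the other replicate fell from 95.2% in the 3000 strongest peaks of replicate 5 to 51.4% in its 3000 weakest, and from 98.1% to 49.7% in replicate 7. When only the 8574 strongest peaks of each were compared the shares were 75.3% and 76.4%, and with the 2143 strongest of each 74.2% and 74.5%, against 3.90% and 3.94%, and 0.933% and 0.952%, with moved peaks. Across the 23202 overlapping peaks of replicate 5 the values of both replicates had a Spearman rho of 0.708, which is across peaks that are not independent replicates, and the summits lay a median of 41 bp apart. Of the IDR peaks, 97.5% overlapped a peak in both replicate lists, a share partly fixed by the derivation of the IDR set from these lists. In the 8574 strongest peaks of both replicates, 75.5% of the IDR peaks were found.

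**Figure D1:**
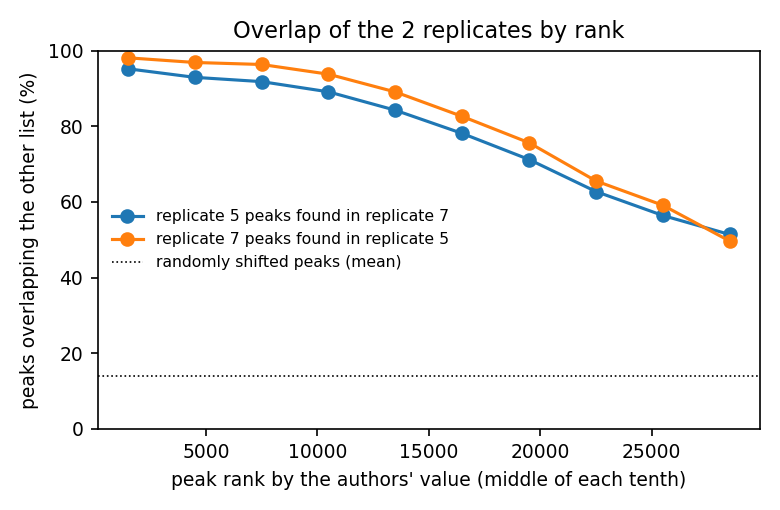
Share of each replicate's peaks (%) that overlap a peak of the other replicate by at least 1 bp, plotted against peak rank by the authors' value in steps of 3000 peaks. Both lines start above 95% and end near 50%, and the dotted line marks the 14% found on average with randomly moved peaks.

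CG12769 peaks gathered at promoters and in introns and were scarce in coding sequence. Of the 8574 IDR summits, 3447 lay within 500 bp of a transcription start site (TSS), or 40.2% (95% exact interval 39.2 to 41.2), against 13.6% of bases. This is a ratio of 2.96 (exact binomial test, two-sided, p below 1e-300). Coding sequence farther from a TSS held 0.921% of summits and 13.7% of bases, a ratio of 0.0670, and the 3' UTRs held 1.05% against 4.44%, a ratio of 0.237 (adjusted exact p = 2.02e-73). Introns held 42.8% of summits against 39.5% of bases, a ratio of 1.08 (adjusted exact p = 1.05e-09), and intergenic sequence 13.2% against 27.1%, a ratio of 0.486 (adjusted exact p = 1.73e-213). The p for coding sequence was below 1e-300, and all were adjusted by the Benjamini-Hochberg method over 7 categories. Noncoding exons held 1.06% of summits against 0.821% of bases (adjusted exact p = 0.0193). The 5' UTRs, with 0.805% against 0.780%, did not pass the test (adjusted exact p = 0.759), but did over the whole pooled list, with 1.06% (adjusted exact p = 1.73e-07). In that list the ratios were 0.111 for coding sequence and 0.387 for 3' UTRs, less far below their share of bases. Among the 3447 promoter summits, 63.5% lay upstream of the nearest TSS or at it (exact binomial test, p = 2.32e-56), and the median position was 50 bp upstream, written as an offset of -50 bp. The excess in introns and noncoding exons was lost in the 2143 strongest IDR peaks, where introns held 37.4% and noncoding exons 0.653% of summits. For noncoding exons it also missed the threshold without replicate 5 and without replicate 7 (adjusted exact p = 0.123 and 0.106).

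**Figure D2:**
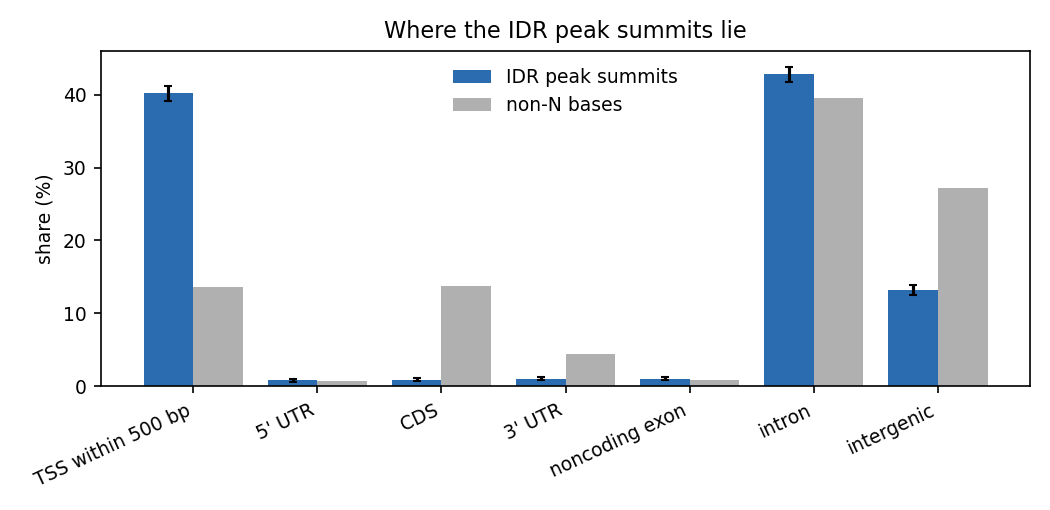
Share (%) of the 8574 IDR summits in each annotation category (blue, with 95% exact binomial intervals) beside the share of non-N bases in that category (grey). Promoters hold 40.2% of summits and 13.6% of bases, and coding sequence holds 0.921% and 13.7%.

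Strong peaks lay at promoters more often than weak ones, and weak ones lay in introns more often. Of the 2143 strongest IDR peaks by the authors' value, 49.0% had their summit within 500 bp of a TSS, against 32.8% of the 2143 weakest. The difference was 16.2 percentage points, an odds ratio of 1.97 (Fisher's exact test, two-sided, p = 4.32e-27). In 8 equal steps of rank, the promoter share went from 51.0% down to 31.8%, while the intron share went from 36.5% up to 47.9%. Each replicate's own strongest 8574 peaks gave differences of 14.5 points for replicate 7 and 14.4 for replicate 5. Among these 2143 strongest peaks alone, the difference between their strongest and weakest 535 was 6.92 points (exact p = 0.0276), and over the whole pooled list it was 26.5 points.

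**Figure D3:**
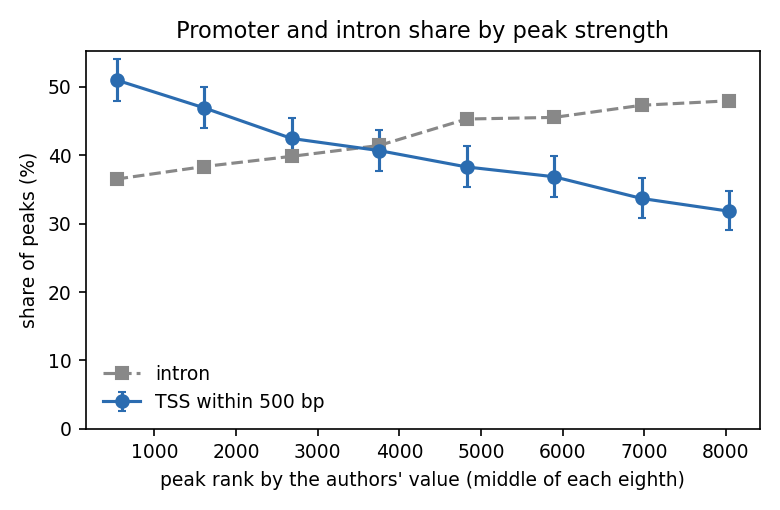
Share (%) of summits within 500 bp of a TSS (blue, with 95% exact binomial intervals) and in introns (grey) in 8 equal steps of IDR peak rank by the authors' value. The promoter share falls from 51.0% to 31.8% as the intron share rises from 36.5% to 47.9%.

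The strongest peak of the set stood on chromosome arm 3R at 23818952-23819600 (dm6), with its summit 87 bp upstream of the nearest TSS of CG33111 and eIF4G2. Its value was 16058.3, against 9527.49 for the peak in second place. That peak lay at 2L:6612474-6612913 in an intron of CG11050, 1024 bp inside the gene from its TSS. Promoter peaks followed at lncRNA:CR44868 (2L:15912284-15913016, value 7522.72), at Ugalt, which encodes a UDP-galactose transporter (X:2703689-2704087, 7293.28), and at CG14100 (3L:19590412-19590809, 7181.6). The peak at 2L:13835259-13835683 (6864.27) lay within 500 bp of TSSs of CenG1A and of the mitochondrial ribosomal protein gene mRpS23. Among the 10 strongest peaks, 3 others lay away from promoters, all in introns: 2L:480847-481311 in ush, a cofactor of GATA factors, where the nearest TSS was that of the zinc finger gene cbt, 1408 bp away; 2L:3301718-3302604 in CG9663; and 3R:11760833-11761472 in the kinase gene Lk6.

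Genes of several kinds made up the rest of the 25 strongest promoter peaks. Chromatin and transcription genes among them were ph-p, a Polycomb group gene (X:2136752-2138268, value 6273.89), Atf3, a bZIP factor (X:1275254-1275740, 5047.71), and Chro, a chromatin protein, whose peak (3L:22878706-22879106, 4660.69) also lay at the TSS of Ssl1, a subunit of the general transcription factor TFIIH. The peak at 3L:18800701-18801678 (4136.77) lay between lncRNA:CR45939 and ftz-f1, a nuclear receptor. Genes that act on RNA or in protein synthesis were PNPase (3R:31404480-31404848, 5025.6), eIF6, next to asRNA:CR45928 (2R:23850193-23850586, 4838.7), mRpS10, whose promoter peak was shared with the methyltransferase gene Art3 (3R:15229348-15229728, 4374.88), and Elp6 of the Elongator complex (3R:13364103-13364678, 4181.81). The peptide-processing genes amon, a prohormone convertase (3R:26714188-26714577, 4774.23), and Pal1, an amidating lyase (2R:9959691-9960126, 3582.75), were in the group, as was moody, a receptor of the glia that form the blood-brain barrier (X:2050116-2050486, 3375.05). The others stood at CG1888, CG9147 with Fbw5, px, MFS10, CG5611 with the GTPase gene Mtl, CG8320 with Pex11ab, CG30457, Shc with Atat, and tank with CG12194, with values from 3589.71 to 5757.44. Each of these 25 peaks ranked among the first 77 in both replicates, with Pal1 at 77 and Art3 at 53 in replicate 5 and moody at 75 and CG30457 at 71 in replicate 7.

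Per Mb, peaks were spread nearly evenly over the large autosome arms and were fewer on the X and fewest on the small chromosome 4. The IDR set held 57.8 peaks per Mb on the X and 27.0 on chromosome 4, against 63.8 on 2L, 67.8 on 2R, 67.8 on 3L and 64.5 on 3R. Relative to bases, the X held 0.902 times its share (1358 peaks, 15.8% against 17.6%, adjusted exact p = 6.59e-05) and chromosome 4 held 0.422 times (36 peaks, adjusted exact p = 1.44e-08). Arms 2R and 3L were both at 1.06 times (adjusted exact p = 0.0174 and 0.0130; 3L did not pass without replicate 7, at 1.04 and 0.0577), while 2L at 0.995 and 3R at 1.00 did not pass (exact binomial tests, two-sided, Benjamini-Hochberg over 6 arms). Among the 2143 strongest peaks only chromosome 4 passed, with 6 peaks and a ratio of 0.281 (exact test), and the X ratio was 0.959. Over the whole pooled list 2R was at 0.945, below its share, and 2L at 1.06, above it. Chromosome 4 was at 0.689 in that list, and at 0.569 when IDR peaks were set against protein-coding TSS positions. Against those positions 2L, at 0.930, was as low as the X, at 0.931, and 3L was at 1.145 (adjusted exact p = 0.00327, 0.00554 and 5.90e-10).

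Among the gene lists, muscle genes and genes of the cytoplasmic ribosome had the largest shares of members with a CG12769 promoter peak. The share of chemosensory receptor genes was among the smallest. An IDR summit lay within 500 bp of a TSS of 2975 of 13945 protein-coding genes, or 21.3%. Of 26 gene lists fixed in advance, 6 had such a peak at more of their genes than other genes did and 5 at fewer, and 15 did not pass the test (Fisher's exact test, two-sided, Benjamini-Hochberg over the 26 lists). With the 2143 strongest IDR peaks alone, 4 of these 11 calls remained: muscle (8 of 32), cytoplasmic ribosomal protein (24 of 86), histone and chemosensory receptor genes. How active the genes were in these embryos was not measured, and a control library was not analysed. The shares therefore do not show that CG12769 selects these kinds of genes.

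In muscle, 21 of 32 marker genes had a promoter peak, or 65.6% (95% exact interval 46.8 to 81.4), an odds ratio of 7.08 (adjusted exact p = 5.39e-07). Part of this goes with the number of TSSs these genes have: against genes with as many TSSs, a comparison added after the data were seen, 12.2 would have a peak and the odds ratio was 3.002 (adjusted permutation p = 0.00195), below the 3.57 of cytoplasmic ribosomal protein, 3.23 of tracheal and 3.03 of heat shock protein genes. Without that matching, the muscle odds ratio was 3.91 in the 2143 strongest IDR peaks and 4.35 with a TSS distance of 200 bp. Over the whole pooled list it was 18.2, with 29 of 32. The strongest peaks were at sls, which encodes a titin-like protein of the sarcomere (3L:2115716-2116054, value 1424.29), at kirre, which takes part in myoblast fusion (X:3099154-3099563, 1293.13), at the troponin C gene TpnC73F (3L:17045601-17046130, 1149.73) and at the Z-disc gene Zasp52 (2R:15816725-15817117, 1000.98). Among cytoplasmic ribosomal protein genes 48 of 86 had a peak, or 55.8% (44.7 to 66.5), an odds ratio of 4.72 (adjusted exact p = 3.48e-11; 7.22 with 57 of 86 without replicate 5, and 4.34 without replicate 7), led by RpL7 (2L:10200869-10201199, 1734.06), RpS27 (1566.65), RpL23A (1272.0) and RpL14 (1190.52). Mitochondrial ribosomal protein genes had peaks at 25 of 73, an odds ratio of 1.93 (adjusted exact p = 0.0251), with mRpS23, mRpS10, mRpL23 and mRpL41 first. When each peak was given only to the gene with the nearest TSS, that list dropped to 10 of 73 and an odds ratio of 0.740 (adjusted exact p = 0.640; the other alternatives gave 0.00026 to 0.326), so its call depends on peaks shared with a neighbouring gene.

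Signalling genes of the embryo had peaks at 20 of 44, an odds ratio of 3.09 (adjusted exact p = 0.00139). First among them were the EGF receptor ligand gene spi (2L:19575559-19576166, value 1440.83), the repressor gene brk of the Dpp pathway (760.03), Raf (598.67) and Stat92E (597.32). The signalling call ended in the 2143 strongest peaks, with 6 of 44 and an odds ratio of 1.85 (adjusted exact p = 0.326). Heat shock protein genes had peaks at 12 of 27, an odds ratio of 2.96 (adjusted exact p = 0.0238), led by Hsp83 (984.1), Hsp27 (879.4), DnaJ-1 (595.1) and Hsp22 (565.97). The call ended without replicate 7, where 9 of the 27 had one and the odds ratio was 1.78. It also ended, at ratios nearer the main one, in the pooled list (2.34, adjusted exact p = 0.0963) and with a TSS distance of 1000 bp (2.35, 0.106). Tracheal markers had peaks at 8 of 17, an odds ratio of 3.28 (adjusted exact p = 0.0380). They included pio and dpy, whose proteins belong to the apical matrix of the tube, the FGF ligand gene bnl and the chitin deacetylase gene verm, with values from 375.7 to 752.0. That call was close to the threshold: before older list names were matched by hand, a step added after the first table of lists had been seen, 7 of 15 had a peak, with an odds ratio of 3.23, and the list did not pass (adjusted exact p = 0.0599). It also ended at nearly the same ratio without replicate 7 (3.17, adjusted exact p = 0.0617), with a TSS distance of 1000 bp (3.31, 0.0595) and against genes with as many TSSs (3.23, adjusted permutation p = 0.0519), and in the 2143 strongest peaks (1.56, 0.537). The tracheal call held over the whole pooled list, with 14 of 17 (8.75, adjusted exact p = 0.000263), and without replicate 5 (3.22, 0.0355). It also held at 200 bp (4.37, 0.0111) and with 1 gene per peak (4.16, 0.0161).

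The lists that carried fewer peaks were those of chemosensory receptors, histones, seminal fluid proteins, antimicrobial peptides and small RNAs. The chemosensory receptor and seminal fluid lists had been included beforehand as a negative set, of genes not used in embryos. Chemosensory receptor genes had peaks at 4 of 179, or 2.23%, an odds ratio of 0.0831 (adjusted exact p = 2.51e-12), at Ir60e, Gr39a, Ir94c and Gr63a. Histone genes had peaks at 3 of 115, an odds ratio of 0.0979 (adjusted exact p = 6.61e-08), and these were the variant and replacement genes His2Av, His4r and His3.3A outside the repeated histone cluster. How the authors' alignment treated repeated sequence such as that cluster is not given in the sources used here. The copies of the cluster were tested as separate genes, though they are not independent places. Whether a peak could be called there is unknown, so this call does not show that histone genes lack binding. Seminal fluid protein genes had a peak at 1 of 47, Sfp26Ad (adjusted exact p = 0.00134). Antimicrobial peptide genes had none in 23, which allows a share of up to 14.8% (exact 95% bound, adjusted exact p = 0.0238), and over the whole pooled list they had peaks at 8 of 23, an odds ratio of 0.997. That call also ended in the 2143 strongest peaks, without replicate 7 (1 of 23, adjusted exact p = 0.118), at TSS distances of 200 and 1000 bp (0.0508 and 0.0510), with 1 gene per peak (0.0564) and against genes with as many TSSs (adjusted permutation p = 0.165). Small nuclear and nucleolar RNA genes had peaks at 37 of 306, or 12.1% against 19.3% of other genes of all kinds (adjusted exact p = 0.00358), with snRNA:7SKa the strongest (3R:7474552-7475001, value 2098.61). With a TSS distance of 1000 bp the odds ratio of that list was 1.04, and against genes with as many TSSs it was 0.875, with 41.5 expected (adjusted permutation p = 0.650), so the call did not hold once the number of TSSs was allowed for.

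Markers of other embryonic tissues did not pass the main test in either direction. Glial markers had peaks at 7 of 16 (adjusted exact p = 0.117), including moody and the FGF receptor gene htl, neuronal markers at 8 of 33 (0.873), including elav with a value of 1611.5, fat body markers at 4 of 16 (0.878) and hemocyte markers at 2 of 19 (0.632), ush and PPO3. Gut markers (fkh, dve and Pdp1) and germline markers (gcl, nanos and vas) each had peaks at 3 of 18 (adjusted exact p = 0.878). Homeotic, gap and segmentation genes had peaks at 6 of 33 (0.878), of which hry was the strongest with 2251.4. The same held for translation factors with 13 of 52 (0.715), oxidative phosphorylation subunits with 18 of 87 (1.00), proteasome subunits with 6 of 48 (0.275), spliceosome components with 5 of 32 (0.715), tRNA genes with 62 of 295 (0.632), cuticle proteins with 16 of 120 (0.0713), cell cycle genes with 9 of 39 (0.878), and insulator and promoter-binding proteins with 8 of 23 (0.235). The last list included Chro, Cp190, Trl and MESR4. Some of these passed under an alternative. Without replicate 5, 11 of 23 insulator and promoter-binding genes had a peak (odds ratio 3.32, adjusted exact p = 0.0157). tRNA genes had peaks at 177 of 295 over the whole pooled list, 60% against 32.6% of other genes (odds ratio 3.10, adjusted exact p = 2.66e-20), and passed at a TSS distance of 1000 bp (1.43, adjusted exact p = 0.0215) and against genes with as many TSSs (1.73), while in the 2143 strongest peaks the ratio was 0.610. Glial markers passed with 1 gene per peak (3.64, adjusted exact p = 0.0394), proteasome subunits were lower over the pooled list (0.318, adjusted exact p = 0.00581), and cuticle proteins were lower in the strongest peaks (0.196), without replicate 5 (0.514) and at 200 bp (0.302).

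**Figure D4:**
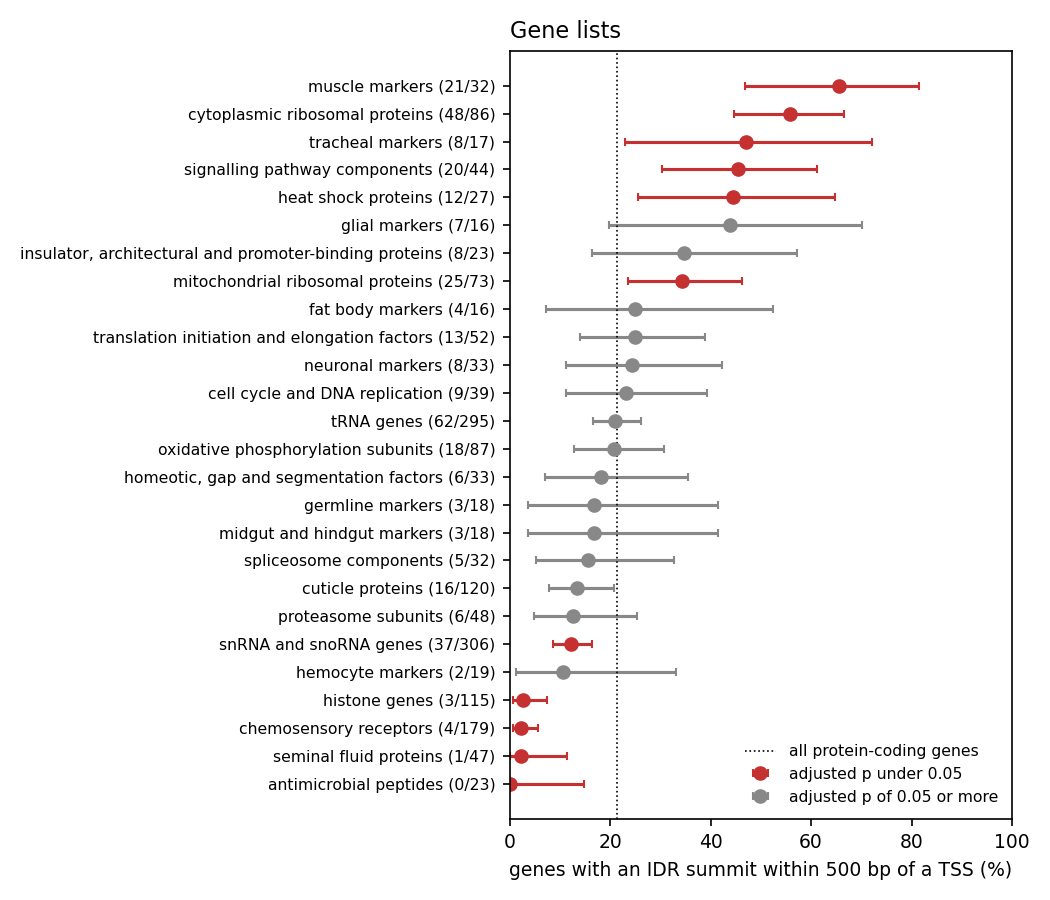
Percent of the genes of each list with an IDR summit within 500 bp of a TSS, with 95% exact binomial intervals and, in brackets, genes with a peak over genes in the list. Muscle markers and cytoplasmic ribosomal protein genes sit well above the dotted line at 21.3% of protein-coding genes, and the RNA gene lists were tested against all genes (19.2% with a peak).

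GAGA factor sites and some of the sequences known from promoters were more frequent under the summits than beside them. Of 25 consensus sequences fixed in advance, 11 were more frequent within 100 bp of the IDR summits than in flanking windows 600 bp away and 3 were less frequent (Fisher's exact test, two-sided, Benjamini-Hochberg over the 25; 8574 summit and 15230 flanking windows). GAGAGAG, the site of Trl and Clamp, was in 6.92% of summit windows and 3.49% of flanks, an odds ratio of 2.05 (adjusted exact p = 3.50e-30). Ohler motif 7 was in 9.34% against 5.61% (1.73, adjusted exact p = 1.68e-25), and the DNA replication-related element bound by Dref, TATCGATA, in 1.89% against 0.624% (3.07, adjusted exact p = 1.20e-17). The M1BP motif GGTCACACT was in 1.10% against 0.295% (3.74, adjusted exact p = 1.88e-13). Also higher were the cores of BEAF-32 with 26.8% against 22.1% and CTCF with 5.97% against 3.99%, the sites of Grainyhead, Forkhead and Mef2, and the E-boxes CAGCTG and CACATG, with odds ratios from 1.14 to 1.55 and the largest adjusted p at 0.00597. The call for CACATG ended without replicate 5 (1.05, adjusted exact p = 0.372). Homeodomain sites (TTAATTA) were lower with 6.50% against 9.41% (0.669, adjusted exact p = 1.19e-14), as were those of TCF with 2.62% against 3.99% (adjusted exact p = 7.20e-08) and Pho with 2.52% against 3.41% (adjusted exact p = 0.000267). The Pho call ended over the whole pooled list (0.935, adjusted exact p = 0.144). The TATA box (0.914), the Initiator (1.02) and Ohler motif 6 (1.03) did not pass. Ohler motif 6 passed in opposite directions without replicate 5 (1.24, adjusted exact p = 0.000713) and without replicate 7 (0.845, adjusted exact p = 0.0121), and the TATA box passed as lower without replicate 7 (0.835, adjusted exact p = 0.000476) and over the whole pooled list (0.926, adjusted exact p = 0.00693). Among the 2143 strongest peaks 7 of the 14 kept their call. The odds ratio of the M1BP motif fell to 1.47, and those of Mef2 to 1.28, Forkhead to 1.14 and CAGCTG to 1.11. Those of Grainyhead (1.60), CACATG (1.24) and Pho (0.738) were about as large as before, in a set with fewer peaks.

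Against promoters without an IDR peak, read at the same distances from the TSS, 8 of the 14 calls remained. These background promoters had no IDR summit within 1000 bp but could hold weaker peaks of the pooled list, so they are not known to be unbound. Those of Dref, M1BP, BEAF-32 (odds ratio 1.11), Forkhead (1.12), Pho (0.890) and Mef2 ended, the last at a ratio of 1.38 (adjusted exact p = 0.399) in a comparison with fewer windows, 3447 on each side. TATCGATA was in 4.06% of promoters with an IDR peak and 3.74% of those without (odds ratio 1.09), and GGTCACACT in 2.47% and 2.41% (1.02). GAGAGAG kept its excess with 8.59% against 3.16% (2.88), as did Ohler motif 7 with 14.0% against 8.76% (1.70), and the AP-1 site TGASTCA was in 2.29% against 1.10% (2.10, adjusted exact p = 0.000596; 0.440 against flanks). Promoters with an IDR peak had fewer TATA boxes, 8.12% against 11.8% (0.659, adjusted exact p = 2.60e-06), which were not among the calls against flanks. They also had fewer matches to Ohler motif 6 (0.779, adjusted exact p = 0.0254) and to the Initiator (0.894, adjusted exact p = 0.0446). Summit windows had 43.7% G and C bases on average and flanks 40.9%. Promoters with an IDR peak had 44.3% and those without 40.6%. Summit windows had 42.4% without replicate 5 and 45.2% without replicate 7. Neither the motif tests nor the word search below was matched on base content. Lower shares of sequences rich in A and T, and their shifts between replicates, cannot be told apart from it.

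A search of all 8-base words, ranked on the odd-numbered peaks and tested on the even-numbered ones, returned words outside the preset list. All 10 words re-tested passed on the 4287 held-out summit windows (Fisher's exact test, two-sided, Benjamini-Hochberg over the 10). CACTGAGA was in 2.17% of them and 0.603% of flanks, an odds ratio of 3.66 (adjusted exact p = 5.53e-13). The related words ACACTGAG (3.55), CTGAGAGA (3.39) and CTCAGTGC (2.76) passed with it. CACTGTGC was in 2.80% against 0.982% (2.90, adjusted exact p = 7.05e-13). GAGAGAAA (2.11), ACACACAC (1.77) and CACACACA (1.70) were also more frequent, while AAAAAAAA, in 7.11% against 12.96%, and TAAAAAAA, in 3.99% against 7.48%, were less frequent. Which words led the search moved with the peaks used: 4 of the 10 passed again in the 2143 strongest, and 5 and 3 when it was run on the top peaks of replicate 7 and replicate 5 alone. Main words outside a run's first 10 were not re-tested. Words with ACAGTG, or CACTGT on the other strand, passed in each of these runs: CCACTGTA, CACTGTAC, ACAGTGGA and CACTGTGC in the strongest, and CACAGTGG, ACAGTGGG and CACTGTGC in each replicate. None was re-tested over the pooled list or against promoters without an IDR peak.

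The CG12769 gene itself (FBgn0033252, 2R:8052080-8065554, minus strand, 13475 bp) held many peaks. The IDR set had 13 peaks over it, with 12 summits inside the gene, and the pooled list had 19. Replicate 5 had 21 and replicate 7 had 18. The strongest lay in an intron at 2R:8062312-8062970, with a value of 4425.35 and rank 21 of the 8574. Next was the intronic summit at 8060972, with a value of 2408.55 and rank 74. A peak with its summit just upstream of the gene's start lay at 2R:8065549-8065858 (1007.23) and reached only a few bases into the gene. Among peaks overlapping the gene, replicate 7 had a counterpart and replicate 5 had none. A replicate 5 peak starting just outside the gene would not be counted, so its absence from replicate 5 was not shown. The other IDR summits lay in introns, in the 5' UTR, within 500 bp of an internal TSS and, for 1 of them, in the 3' UTR. The best rank at the gene was 15 in replicate 5 and 31 in replicate 7.

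**Figure D5:**
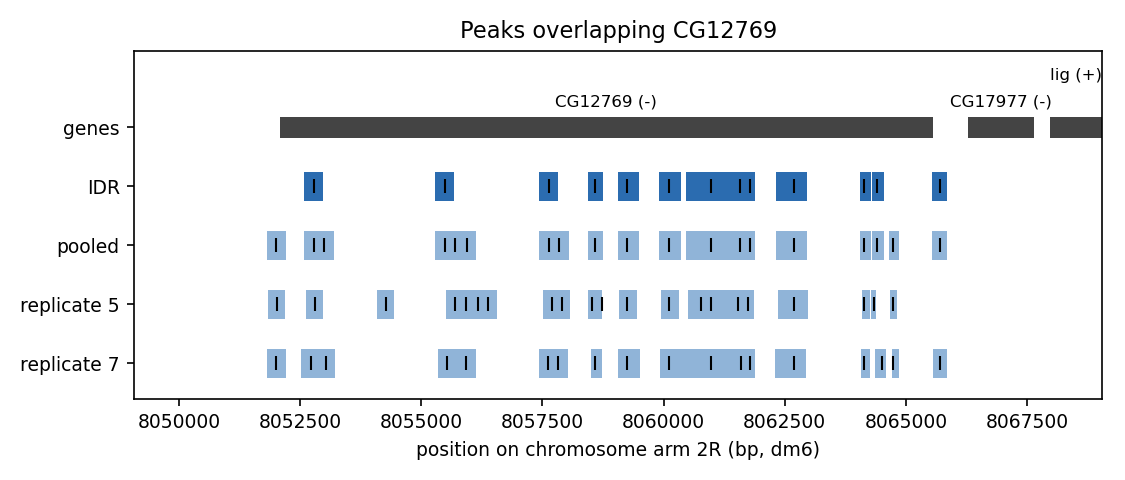
Map of chromosome arm 2R around CG12769 (position in bp, dm6) with gene spans on top and the peaks of the IDR set, the pooled list and both replicates as bars, with summits as black lines. The 13 IDR peaks run from the 3' end of the gene to just past its start at 8065554.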

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

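Tests chosen only after the result was seen were those on a single summit per 1000 bp, on lists matched by the number of TSSs, on list names without matching by hand, and on other peak sets for the CG12769 gene. The replicate overlap, the promoter share and its fall with peak strength kept their direction and stayed past the threshold under every alternative run for them, with promoter shares from 26.0% to 51.9% and overlaps from 59.4% to 76.4%. In the search for words, 8 to 10 of 10 passed under each alternative, but only 3 to 5 of them were words of the main search, and words of 6 and 7 bases cannot be set against these. The search was run anew each time, so main words outside a run's first 10 were not re-tested. The cause of the changes below was not tested, except that the set of the 2143 strongest holds fewer peaks and that single-replicate sets rest on fewer samples. Depth is unknown, so it cannot be said which changes it limits.

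Among the 2143 strongest IDR peaks, 1 chromosome arm instead of 4 passed, 5 gene lists instead of 11, 7 motifs instead of 14, and 7 peaks instead of 13 lay over CG12769. Noncoding exons held 0.653% and introns 37.4% of summits, both below their share of bases. Arm ratios turned to 1.09 on 2L, 0.978 on 3L and 0.951 on 3R. Odds ratios turned to 0.610 for tRNA genes, 0.631 for cell cycle genes, 0.753 for neuronal and 0.778 for fat body markers, and 0.766 for the GATA motif. Over the whole pooled list the arm ratios turned to 1.06 on 2L, 0.945 on 2R and 0.979 on 3R. The odds ratios of translation factors (0.908), spliceosome components (1.12), gut markers (1.87), segmentation genes (1.76) and the Initiator motif (0.984) turned as well.

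Against protein-coding TSS positions the ratio on 2R was 0.977. With a TSS distance of 200 bp, odds ratios turned to 1.02 for oxidative phosphorylation, 0.669 for tRNA genes and 0.891 for cell cycle genes. At 1000 bp, 7 lists passed, and small nuclear and nucleolar RNA genes were at 1.04, fat body markers at 0.978 and gut markers at 1.13. With 1 gene per peak, mitochondrial ribosomal proteins were at 0.740, tRNA genes at 0.738 and segmentation genes at 1.04. Without the matching by hand 10 lists passed, all of them among the 11. Matched on the number of TSSs, 9 lists passed, 8 of them among the 11, and the other was tRNA genes (1.73). Cell cycle genes were then at 0.945, neuronal markers at 0.632 and fat body markers at 0.774. In windows of 50 bp to each side the CACGTG motif was at 0.959 and the TATA box at 1.00. Against promoters without an IDR peak, Ohler motif 6 was at 0.779, CACGTG at 0.904, the Initiator at 0.894, Su(Hw) at 0.626 and GATA at 0.921.

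Leaving out a replicate gave 7 to 13 gene lists, with 7 when replicate 7 was left out, all among the 11, and the 13 included insulator and promoter-binding proteins (3.32). The ranges over both replicates were 0.746% to 0.945% for the 5' UTR share, 0.988 to 1.03 for the ratio on 2L and 0.988 to 1.00 on 3R. For lists they were 0.955 to 1.22 for tRNA genes, 0.918 to 1.08 for cell cycle genes, 0.644 to 0.958 for neuronal, 0.821 to 1.20 for fat body, 1.03 to 1.37 for gut and 0.722 to 1.02 for germline markers. For motifs they were 0.845 to 1.24 for Ohler motif 6, 0.835 to 1.04 for the TATA box, 0.931 to 1.05 for GATA and 0.816 to 0.931 for the heat shock element. Of the single lists under all alternatives, 173 values kept direction and side of the threshold, 24 lost the threshold, 9 gained it and 28 changed direction. Of the single motifs, 109 kept both, 15 lost the threshold, 12 gained it and 14 changed direction.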

Other observations

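The tests on the CG12769 gene, on X peaks against TSS positions, on summits in ecdysone genes, on paired ACAGTG words and on repeated elements were chosen only after the result was seen. The word ACAGTG itself was also chosen from a search of these peaks. The 30 genes with the most IDR summits, by count and not by density, were 22.27 to 394.1 kb long. Eip75B, an ecdysone-induced nuclear receptor, held 33, shn, a zinc finger cofactor of Dpp signalling, held 28, sbb held 27, and CG1677 and bun held 23 each. Others among the 30 with the most were kirre and rdx with 20 each, CG46467 with 19, ush and aop with 16 each, and InR, tkv, Svil, klar and the muscle factor Mef2 with 15 each. Whether regulatory genes were in excess among them was not tested. Also among the 30, besides Eip75B, were the ecdysone response genes Hr4 (17), ftz-f1 (16), EcR (15) and Eip74EF (14). A list of 15 such genes, drawn up after these 5 had been seen, held 114 summits against 43.4 on average in sets of genes matched on length, a difference that cannot be separated from the choice of the list. Its 10 members outside the 30 genes with the most summits held 19, against 22.0 on average in matched sets. Eip93F, Hr38, Hr51, Hr78 and Blimp-1 held none. No list fixed beforehand was tested, so these counts speak neither for nor against the ecdysone pathway, and whether gene length accounts for the summits of the 5 was not settled.

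Peaks listed in a single replicate were few among the strongest 8574 of each. Replicate 5 had 559 that overlapped nothing in replicate 7, of which 58.5% were at promoters, with 45.6% G and C bases. Its other 8015 had 39.2% at promoters and 45.2% G and C. Replicate 7 had 240, of which 50.4% were at promoters, with 36.6% G and C, against 40.3% and 42.6% in its other 8334.

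The word ACAGTG, read on the other strand within the 8-base word CACTGTGC, was more frequent under strong peaks. Within 100 bp of their summits it lay mostly 60 bp or more away, in a broad band. It came from a search of these same IDR peaks, so its p-values in them are not from held-out peaks. It was within 100 bp of the summit in 18.1% of the 2143 strongest and 10.6% of the 2143 weakest IDR peaks (odds ratio 1.86, Fisher's exact p = 3.49e-12), and in 7.77% of flanks. Most of this came from the strongest eighth of the IDR peaks, with 22.3% of 1071; the next eighth had 13.9%, and the 3 after it 12.6% to 12.97%. In each replicate's own peaks the odds ratio was 1.70 for replicate 5 and 1.72 for replicate 7. Words 60 to 110 bp from the summit mostly read toward it: among the 2143 strongest peaks 259 did and 91 read away (exact binomial p = 8.29e-20). The direction was predicted only for pooled peaks outside the IDR set, so this p describes the strongest peaks and tests no prediction. Of the 2143 strongest peaks, 60 had a word on each side of the summit, both reading toward it, where 7.64 would be found if the sides were independent (odds ratio 25.2, Fisher's exact p = 9.41e-45). Words were sought only 60 to 110 bp from the summit. The median spacing of these pairs, 169.5 bp, is therefore no evidence of a preferred distance. Such pairs were also in 30 of the 6431 other IDR peaks, with an odds ratio of 12.95, and in 26 of the 21426 pooled peaks outside the IDR set, with 7.00. Of 179 other words made of the same bases, the highest had 11 pairs in the strongest peaks and the median was 0. The pair with the strongest peak stood at the promoter of CenG1A (2L:13835366-13835549, spacing 178 bp), and others lay at CG1635, larp, Rtnl1, mrt and PAN3 promoters and in introns, with the nearest TSS that of for or NFAT. The CenG1A stretch, from word to word, reads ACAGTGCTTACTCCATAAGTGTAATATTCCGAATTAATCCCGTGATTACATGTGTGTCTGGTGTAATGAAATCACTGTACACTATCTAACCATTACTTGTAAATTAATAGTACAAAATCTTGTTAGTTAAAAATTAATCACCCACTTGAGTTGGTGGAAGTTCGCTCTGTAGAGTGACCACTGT.

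For this pattern, promoter location of strong peaks was excluded by an odds ratio of 1.99 in peaks farther than 500 bp from a TSS (95% interval 1.58 to 2.503). Base composition was not settled. Of the 180 words of the same bases, 1.11%, ACAGTG included, had as large a ratio of shares. AGGTAC had a larger one, 1.714 against 1.702. ACAGTG had been chosen from these peaks, so a high rank could follow from the choice. A sequence read at the summit itself was excluded, because the density of the word within 25 bp of the summit was 0.322 times that at 75 bp or farther (exact binomial p = 1.27e-16). In the pooled peaks outside the IDR set, words reading toward the summit were 1.18 times as many as those reading away (exact binomial p = 0.00545). This met the rule set beforehand for rejecting chance orientation. The test took all words as independent, though summits close together can count the same word, so it does not exclude chance orientation by itself. Copies of a repeated element that keep an unbroken run of 16 bases were not seen, as 0% of 90 stretches between paired words shared 16 bases with another stretch. Copies that differ more than this would be missed, so they stay open. What gives rise to the pattern stays open; the design names no biological contrast, so no biological explanation was tested.

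The many peaks over CG12769 were not of a kind that genes of its length reach by chance. Its 0.891 IDR summits per kb compared with a median of 0.0680 in 549 protein-coding genes within 20% of its length, and 0.182% of them, itself alone, was as dense. Extra copies of the tagged gene, which would add reads over all of its sequence, exons included, stay open: 5 of its 17 pooled-list summits were in exons, or 29.4%, against 6.50% in other genes (odds ratio 5.996, 95% interval 1.65 to 18.3, Fisher's exact p = 0.00372), and 38.2% of its bases are exonic. The labels do not say which sequence the transgene carries, and binding of the protein to its own gene was not tested apart from this.

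Whether the lower number of X peaks comes in part from the single X of males in a mixed-sex sample was not settled. When X values of the pooled list were raised by a factor of 4/3 and the same number of top peaks was taken, the ratio of X peaks to X bases went from 0.902 (95% interval 0.858 to 0.947) to 1.19 (1.14 to 1.24), past 1. Raising the values of an arm raises its share of top peaks whatever the cause of a deficit. The rise therefore cannot decide for or against this explanation. Fewer TSS positions on the X were excluded as the whole cause, since the ratio to protein-coding TSS positions was 0.931 (0.886 to 0.978). With that reference, though, arm 2L was as low, at 0.930, and 3L was at 1.145. A deficit particular to the X was therefore not shown against TSS positions. Median values of IDR peaks were 287.5 on the X and 289.3 on the 4 large autosome arms. No biological explanation was tested.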
